A study of Drosophila melanogaster with 6 samples.

How the data were processed

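L3 lamina neurons were sorted from optic lobes, total RNA was extracted with a column kit, and cDNA libraries were made with a Smart-seq2 protocol and a Nextera kit, per the labels' protocols. The design text gives 3 biological replicates per genotype and says that libraries were prepared and sequenced together. Groups were taken from the genotype labels, 3 WT and 3 dFezf1 samples. The submitters' processing notes name FastQC, STAR, Salmon and DESeq2 and the genome build BDGP6, with no versions. Which of these tools made which column is not given in the sources used here.

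The authors' deposited comparison of dFezf1 against WT lists 13727 genes. Per the file headers it holds a mean normalized count, a signal that is never negative, for each gene over all libraries. Per the file headers it also holds a log2 fold change and its standard error, a test statistic, p-values and adjusted p-values. In the deposited values the p-value equals the two-sided normal tail of the statistic, a score, in all 9755 genes that have one, within 0.001. The authors' adjusted p-values equal the Benjamini-Hochberg values over 9387 genes, the tested genes. The deposited log2 fold changes are shrunken toward 0: in 3798 genes the fold change divided by its standard error differs from the deposited statistic by 1% or more. Fold changes are therefore smaller than the p-values or the group means would lead one to expect in genes with few reads, and also in some with many, such as Ih and chinmo. The deposited group means, named wt and mutant per the file headers, are an abundance signal whose unit is not given in the sources used here. Over 5782 genes, the ratio of mean normalized count to these means had a Spearman correlation of 0.951 across genes with exon length, as for a length-scaled unit. These group means are the authors' and carry no SD.

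A further 12 columns of values per library in the 2 deposited tables carry codes that match no sample label. No column was given a group from its values or its order, and no result here uses them. The planned edgeR fits from counts were therefore replaced by the authors' own comparison, and no depth per library, replicate spread, left-out replicate or other split of the samples is given. The direction of the fold changes was checked against the 2 group means, and the signs were equal in 640 of 640 called genes.

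Gene symbols and positions were taken from the gene identifier, through the gene name table and the annotation of build BDGP6. Of 13503 genes with a position in both, 99.2% had the same start in the deposited table. In 21 genes, 20 of them called, the symbol, position and category in the deposited table are missing or belong to another gene, and those 20 share their adjusted p with other genes. Values were taken to belong to the gene identifier. Exon length supports this for 14 of the 18 genes where both lengths are known, and is nearer that of the other gene for 4, so it was not settled for each gene. TkR99D of the neuropeptide list is among the 21. Categories were given back to the gene they describe. Some 146 identifiers had no name, 6 of them called.

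A gene was called at an adjusted p under 0.05, the threshold fixed before the data were examined. Beside it, calls were counted whose shrunken fold change has a 95% interval (normal, from the deposited standard error) that excludes 0. The 27 gene lists were fixed before the data were examined. Of 864 symbols in them, 30 matched no gene of the table and were left out. Lists were tested with camera (cameraPR, limma 3.58.1, R 4.3.3) on the authors' statistic with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. A correlation between genes was not estimated, since values per library were not used, and a preset of 0.05 was run instead. Called against not called genes were compared between each list, category or arm and the other tested genes by two-sided Fisher's exact tests (SciPy 1.17.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6). The Fisher tests of lists and categories, also by direction, were chosen after the data were seen.

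Named genes followed a rule written in advance: erm; NetA, NetB, slp1, slp2 and lamina subtype factors; the 10 genes with the greatest rise and the 10 with the greatest fall among calls; and up to 4 called members of each list by p. The rule asked for libraries that do not overlap and a mean log2 CPM of at least 3. Since libraries were not used, these became a 95% interval that excludes 0 and a mean normalized count of at least 118.7, the same share of the summed mean normalized counts, which left 291 genes. Further genes were named after their values were seen: ct, dpr3, dpr6, dpr8, kek2, cac, mamo, Eip78C, ths, sNPF, sNPF-R, Ilp2, Ilp3, ChAT, CG5062 and CG18171 in the report, and fmt, rau, bchs, CG14000, trn, Ilp4, Ilp5 and Dsk in the closing observations. Where a group mean was 0 no fold is given.

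On simulated statistics of 9387 genes, camera called 10 of 10 sets of 20 genes shifted by 1 and 7 of 10 shifted by 0.5. Of 90 unshifted sets it called 0 and 4. A set was called here at an unadjusted p under 0.05. The simulated values were independent between genes, so these counts do not give the error rate of the adjusted test on the authors' statistic. The alternatives were an adjusted p under 0.01, no filter on low counts, minimum mean normalized counts of 10 and 100, a minimum log2 fold change of 1, group means above 0, ranks in the set test and the chromosome as the deposited table gives it. Figures were drawn with matplotlib 3.10.9.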

Results

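The series profiled RNA of L3 neurons, one of the neuron types of the lamina, the first relay of the fly visual system. Labelled L3 neurons were sorted by flow cytometry from optic lobes at 24 h after puparium formation. There were 3 WT samples, which carry an FRT40 chromosome, and 3 dFezf1 samples, which carry an allele of dFezf, the transcription factor gene also called earmuff (erm). The sample titles carry dates of 28, 29 and 30 November for WT and of 12, 13 and 14 December for dFezf1. Title date and genotype therefore cannot be told apart. The values below come from the authors' deposited table of dFezf1 against WT, which gives a mean normalized count over all libraries, a shrunken log2 fold change with its standard error (SE) and an adjusted p per gene. Depth per library was not used here, so the SE of each fold change is the precision given beside each value.

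The comparison asked which genes L3 neurons express differently when dFezf is mutant. In the authors' deposited table the netrin gene NetB, which encodes a secreted axon guidance cue, fell by 6.43 ± 0.60 (SE) on the log2 scale, and the forkhead factor gene slp1 rose by 1.52 ± 0.32. Members of the dpr family of immunoglobulin-domain surface proteins moved both ways, with dpr13 up by 7.67 ± 0.63 and dpr6 down by 2.70 ± 0.56 in log2 units in the authors' deposited table. The surface protein gene side-III had a log2 fold change of -8.47 ± 0.47 and the adhesion gene Dscam4 one of 5.28 ± 0.63 in the authors' deposited table. Across the genome, 640 of 9387 tested genes had an adjusted p under 0.05 in the authors' deposited table, 406 higher and 234 lower in dFezf1. For 359 of these genes (223 higher, 136 lower) the 95% interval of the shrunken fold change in the authors' deposited table also excluded 0. Of the 281 others in the authors' deposited table, 266 had 1 group mean listed at 0, and their median mean normalized count was 30.2, against 592 for the 359. Restricting the authors' deposited table to genes with a mean normalized count of at least 100 left 297 calls, 190 higher and 107 lower, and restricting it to genes above 0 in both groups left 254. In the same comparison transcripts of the mitochondrial genome and the progenitor list were shifted upward in a set test with a preset correlation of 0.01. With a preset of 0.05 neither was (camera adjusted p = 0.0804 and 0.151).

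**Figure D1:**
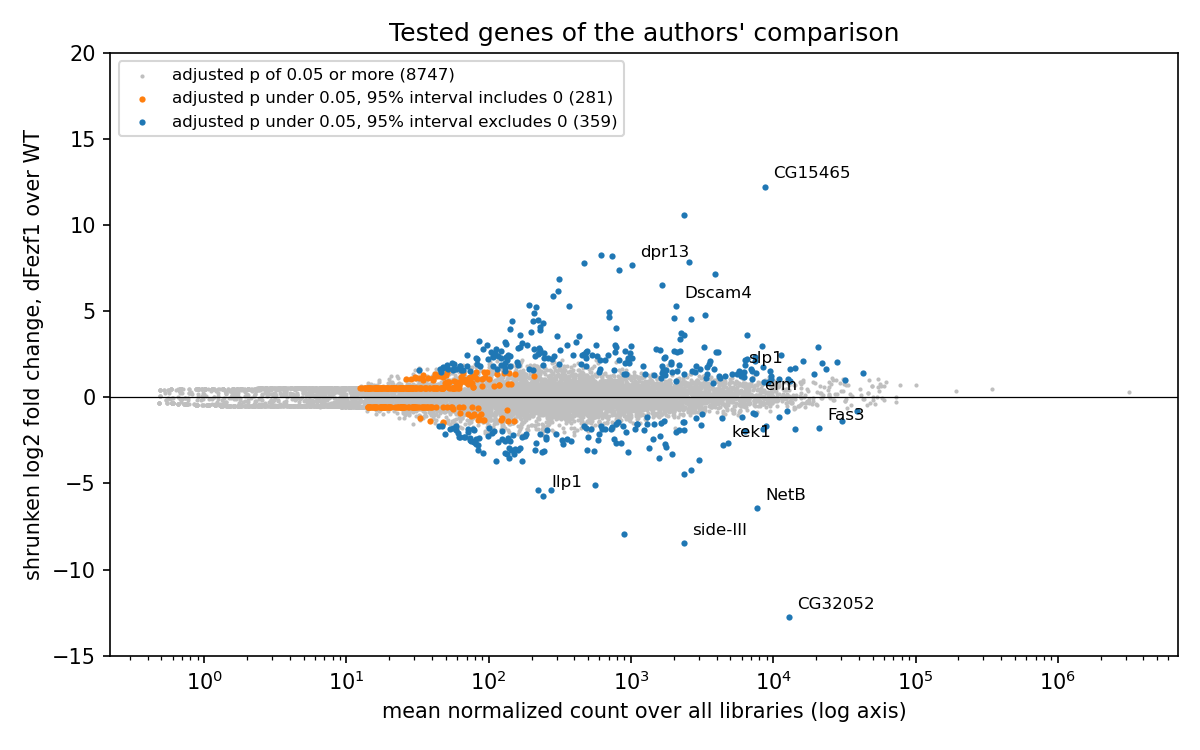
Each point is 1 of the 9387 tested genes, with the mean normalized count over all libraries on a log axis and the shrunken log2 fold change of dFezf1 over WT on the vertical axis, both from the authors' deposited table. Blue points are the 359 genes past adjusted p 0.05 whose 95% interval excludes 0, orange points are the 281 that pass on p alone and sit at low counts, and grey points are the other tested genes.

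The transcript of the mutated gene itself did not differ detectably. In the annotation of build BDGP6, erm (FBgn0031375) lies on chromosome 2L from 1950239 to 1970362 on the minus strand. Its log2 fold change in the authors' deposited table was -0.03 ± 0.30 (SE) with an adjusted p of 0.986, and the authors' mean abundance was 55.1 in WT and 49.2 in dFezf1. A transcript level cannot show a lesion that leaves the transcript in place, so it does not check the labels of these samples.

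NetB and slp1 were to be described whatever their result. NetB (chromosome X, 14686038 to 14749376) went from an authors' mean abundance of 31.5 in WT to 0.119 in dFezf1, with an adjusted p of 2.26e-24 in the authors' deposited table. NetA, the neighbouring netrin gene, had a mean normalized count of 0.218 in the authors' deposited table and received no adjusted p. slp1 (chromosome 2L, 3825675 to 3827099) had an adjusted p of 4.75e-05 in the authors' deposited table, with authors' mean abundances of 51.3 in WT and 144 in dFezf1. Its neighbour slp2 had a log2 fold change of 0.68 ± 0.47 in the authors' deposited table and an adjusted p of 0.545. Of the transcription factors that mark other lamina neurons, 1 of 5 tested was higher in the authors' deposited table (camera adjusted p = 0.458). This was svp, a marker of L1 neurons, with a log2 fold change of 2.08 ± 0.80 and an adjusted p of 0.0224. The authors' mean abundance of svp went from 0.041 in WT to 2.02 in dFezf1, a wider gap than its shrunken fold change. Values per library were not used, so whether all dFezf1 libraries share the rise of svp is unknown. svp did not pass an adjusted p of 0.01. The L2 markers bab1 and bab2 had log2 fold changes of -0.46 ± 0.80 and 0.46 ± 0.73 in the authors' deposited table, and ap and pdm3 had 0.35 ± 0.62 and 0.02 ± 0.58. None of the 4 had an adjusted p under 0.05. bsh, a marker of L4 and L5 neurons, was near 0 in both groups of the authors' deposited table and was not tested.

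In the list of transcription factors of other optic lobe neurons, 5 of 30 tested genes were higher in the authors' deposited table and none lower. mab-21 had a log2 fold change of 4.08 ± 0.76 and ct, a homeobox gene, one of 2.22 ± 0.77 in the authors' deposited table. Whether mab-21 encodes a transcription factor was not examined, and it was counted because the list holds it. slp1 was the third, and ey and TfAP-2, listed at 0 in WT, passed on p with mean normalized counts of 31.5 and 45.3 in the authors' deposited table. As a set the optic lobe factors were shifted upward in the camera test on the authors' statistic with a preset correlation of 0.01 (adjusted p = 0.0149). With a preset correlation of 0.05 they were not (adjusted p = 0.151). The progenitor list was also shifted upward at 0.01 (adjusted p = 0.022) and not at 0.05 (adjusted p = 0.151) or among genes with a mean normalized count of at least 100 (adjusted p = 0.0794). Its called members in the authors' deposited table were svp and E(spl)mgamma-HLH, 2 of 17 tested. The lamina precursor list had 1 of 7 called, gcm, at a mean normalized count of 22.0 in the authors' deposited table and listed at 0 in WT (camera adjusted p = 0.224).

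Families of cell surface proteins changed in both directions. In the dpr list 5 of 20 tested genes were higher and 4 lower in the authors' deposited table, more than among other tested genes (odds ratio 11.3, 95% interval 4.13 to 30.2, Fisher's exact test, adjusted p = 3.46e-05). dpr10 rose by 4.59 ± 0.34 and dpr12 by 4.96 ± 0.76, while dpr3 fell by 2.44 ± 0.37 and dpr8 by 1.22 ± 0.35 on the log2 scale of the authors' deposited table. The median statistic of the list was -0.21 and its mean 1.2 in the authors' deposited table, so the upward camera result (adjusted p = 0.0479, 0.222 with a preset correlation of 0.05 and 0.796 on ranks) rested on the large rises. Of the DIP genes, which encode binding partners of dpr proteins, 1 of 6 was called in the authors' deposited table, DIP-beta, listed at 0 in WT (camera adjusted p = 0.108). The leucine-rich-repeat list had 5 of 24 higher and 6 lower in the authors' deposited table (odds ratio 11.7, 95% interval 4.74 to 28.5, Fisher's exact test, adjusted p = 4.05e-06). kek1 fell by 2.78 ± 0.36, caps by 3.13 ± 0.80 and Lrch by 3.32 ± 0.68, and kek2 rose by 1.47 ± 0.38 on the log2 scale of the authors' deposited table. Lrch was counted because the list holds it, and whether its protein lies at the cell surface was not examined. The set had no shared direction (camera adjusted p = 0.419), and its median statistic of 0.12 and mean of -0.23 in the authors' deposited table differed in sign.

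The adhesion list had 8 of 44 tested genes higher and 3 lower in the authors' deposited table (odds ratio 4.62, 95% interval 2.09 to 9.42, Fisher's exact test, adjusted p = 0.00118). Its direction did not pass (camera adjusted p = 0.136), except with genes above 0 in both groups (adjusted p = 0.0437, upward). Fas3, an abundant homophilic adhesion gene with a mean normalized count of 21140, fell by 1.79 ± 0.21 and Nrx-IV by 2.02 ± 0.39, while the teneurin gene Ten-a rose by 3.73 ± 0.68 on the log2 scale of the authors' deposited table. Ten-a overlaps 2 further genes called higher. In the beat and side families 2 of 20 were higher and 2 lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.106; camera adjusted p = 0.708, and 0.0403 on ranks). side-VI rose by 3.20 ± 0.79 and side-VIII fell by 1.82 ± 0.61 in log2 units of the authors' deposited table, the latter with an adjusted p of 0.0438 that passed neither at a mean normalized count of at least 100 (0.0549) nor above 0 in both groups (0.077). Of the guidance list, 4 of 42 were higher and 2 lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.132; camera adjusted p = 0.419). Besides NetB, the phosphatase receptor gene Ptp99A rose by 2.04 ± 0.34 and the receptor gene Drl-2 by 3.83 ± 0.79 on the log2 scale of the authors' deposited table, and robo2 passed on p with WT listed at 0.

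**Figure D2:**
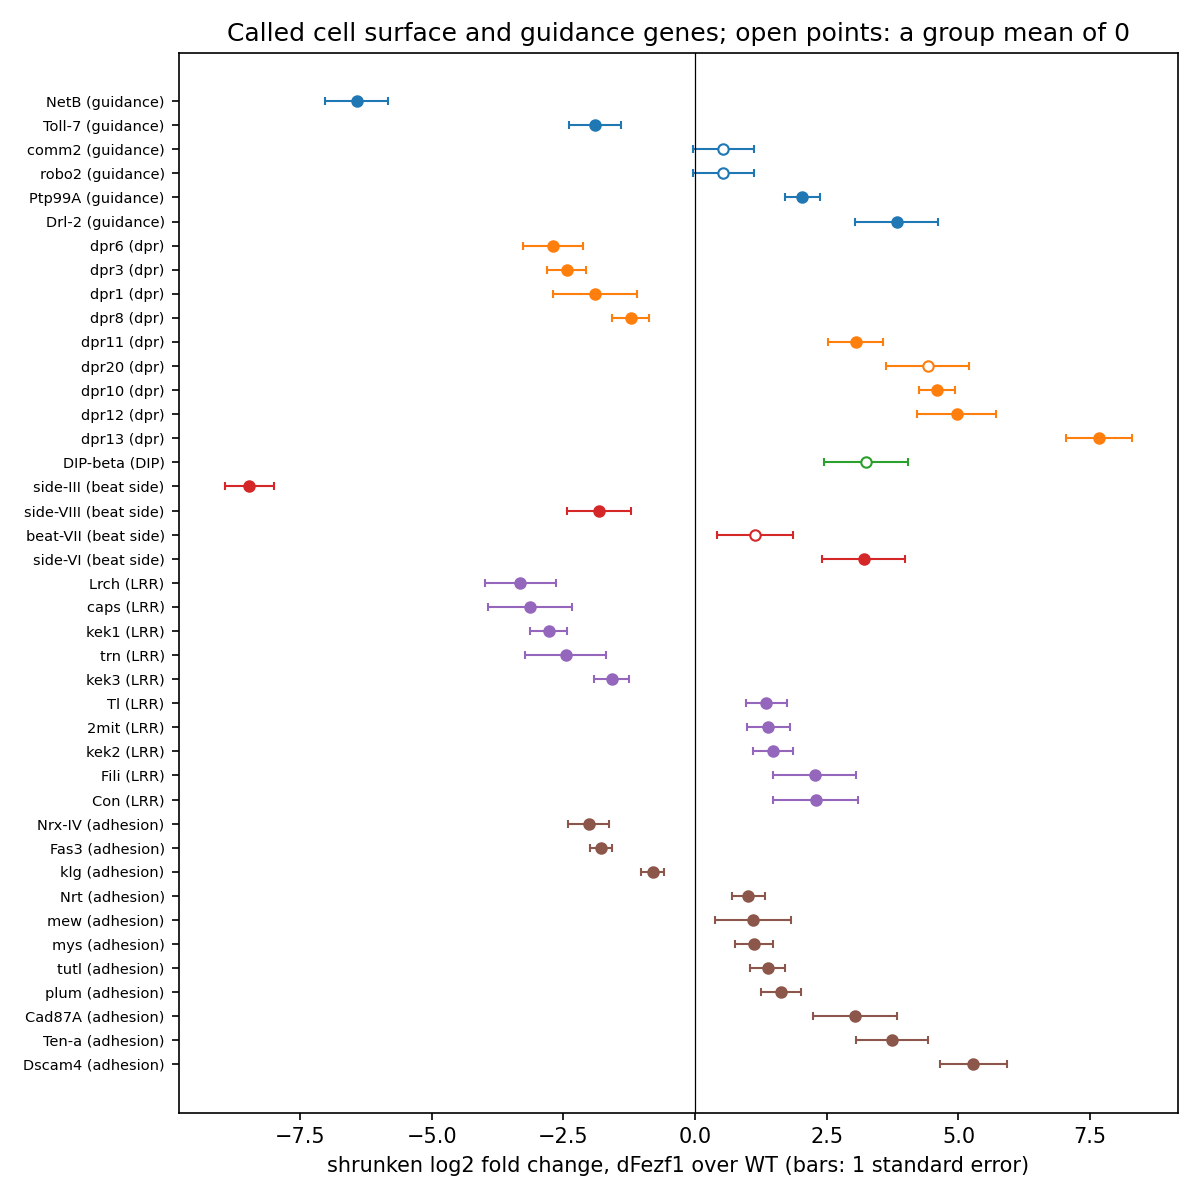
Shrunken log2 fold changes of dFezf1 over WT, with bars of 1 SE, for the called genes of the guidance, dpr, DIP, beat and side, leucine-rich-repeat and adhesion lists in the authors' deposited table. Colours separate the lists and open points mark genes with a group mean of 0; the dpr points span from -2.70 for dpr6 to 7.67 for dpr13.

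Ion channels, receptors and synaptic genes were counted next. Of the ion channel list 6 of 33 tested genes were higher and 2 lower in the authors' deposited table (odds ratio 4.42, 95% interval 1.71 to 10.2, Fisher's exact test, adjusted p = 0.00521). By camera the channels were shifted upward (adjusted p = 0.0416), but not with a preset correlation of 0.05 (adjusted p = 0.222). The calcium-activated potassium channel gene SK rose by 2.37 ± 0.49, the calcium channel gene cac by 1.55 ± 0.40 and the hyperpolarization-activated channel gene Ih by 2.61 ± 0.81 on the log2 scale of the authors' deposited table. The authors' mean abundance of Ih went from 0.0581 in WT to 15.5 in dFezf1, a wider gap than its shrunken fold change, at a mean normalized count of 4068. Values per library were not used, so whether all dFezf1 libraries share the rise of Ih is unknown. Neurotransmitter receptors had 7 of 40 higher and 2 lower in the authors' deposited table (odds ratio 4.01, 95% interval 1.67 to 8.67, Fisher's exact test, adjusted p = 0.00521). The receptors had a camera adjusted p of 0.0479. It was 0.0516 with no filter on low counts, 0.276 at a preset correlation of 0.05 and 0.105 at a mean normalized count of at least 100. nAChRalpha7, a nicotinic receptor subunit, rose by 2.14 ± 0.33 and Octbeta2R by 2.48 ± 0.61 on the log2 scale, while Dop2R was listed at 0 in dFezf1 in the authors' deposited table. No gene of neurotransmitter synthesis or vesicular loading was called among 15 tested in the authors' deposited table (camera adjusted p = 0.143, and 0.0253 on ranks, upward), and ChAT had a log2 fold change of 0.39 ± 0.45. Of the presynaptic list 2 of 38 were higher in the authors' deposited table, Syn by 1.48 ± 0.40 and Sap47 by 1.06 ± 0.35 in log2 units (camera adjusted p = 0.0438, and 0.246 at a preset correlation of 0.05). Sap47 had an adjusted p of 0.0386 in the authors' deposited table, and 0.0692 among genes above 0 in both groups.

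Of the neuropeptide and peptide receptor list, 3 of 35 tested genes were higher and 6 lower in the authors' deposited table (odds ratio 4.78, Fisher's exact test, adjusted p = 0.00288). Among genes above 0 in both groups that excess had an adjusted p of 0.214 (Fisher's exact test), with 2 of 14 called. Of the 6 lower genes 3 are Ilp1, Ilp2 and Ilp3, described below. The camera adjusted p of the list was 0.136. The short neuropeptide F gene sNPF rose by 1.40 ± 0.33 and its receptor gene sNPF-R fell by 1.42 ± 0.41 on the log2 scale of the authors' deposited table. Ilp1, Ilp2 and Ilp3, which encode insulin-like peptides, were each listed at 0 in dFezf1 in the authors' deposited table, at mean normalized counts of 239, 67.7 and 47.0. In the annotation of build BDGP6 these genes lie within the span of CG32052 (chromosome 3L, 9787046 to 9808713), itself called lower. By the positions in the authors' deposited table that gene starts at 9799062 and its span holds Ilp2 and Ilp3 but not Ilp1. The origin of reads in these overlapping genes is therefore uncertain. Among secreted signals and their receptors 5 of 45 were higher and 2 lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.0842; camera adjusted p = 0.419). The excess of calls passed in 3 alternatives by Fisher's exact test: adjusted p = 0.00744 at a mean normalized count of at least 100, 0.0208 where the 95% interval excludes 0 and 0.0158 above 0 in both groups. aos, which encodes an inhibitor of EGF receptor signalling, rose by 2.91 ± 0.45, and the PDGF- and VEGF-related factor gene Pvf3 fell by 2.63 ± 0.32 on the log2 scale of the authors' deposited table. The FGF genes pyr and ths moved in opposite directions in the authors' deposited table, by 2.95 ± 0.75 and -1.49 ± 0.37 in log2 units.

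The ecdysone response and timing list had 6 of 29 tested genes higher and 1 lower in the authors' deposited table (odds ratio 4.38, 95% interval 1.58 to 10.7, Fisher's exact test, adjusted p = 0.00932). Its camera adjusted p was 0.00523, and 0.128 with a preset correlation of 0.05. With genes above 0 in both groups the camera adjusted p was 0.149, and the excess of calls had an adjusted p of 0.81 (Fisher's exact test). chinmo, a temporal identity gene, had a log2 fold change of 2.11 ± 0.80 and mamo one of 1.39 ± 0.45 in the authors' deposited table, Eip63F-1 was listed at 0 in WT, and the nuclear receptor gene Eip78C fell by 0.99 ± 0.32. The authors' mean abundance of chinmo was 0.122 in WT and 9.89 in dFezf1, also a wider gap than its fold change. Whether all dFezf1 libraries share the rise of chinmo is likewise unknown. Transcripts of the mitochondrial genome rose for 5 of 13 tested genes in the authors' deposited table and fell for none (odds ratio 8.6, 95% interval 2.21 to 29.9, Fisher's exact test, adjusted p = 0.00521). As a set they were shifted upward by camera (adjusted p = 0.00523), but not with a preset correlation of 0.05 (adjusted p = 0.0804). mt:ATPase6 rose by 1.78 ± 0.45 and mt:CoI by 1.63 ± 0.46 on the log2 scale of the authors' deposited table. No cytosolic ribosomal protein gene was called among 71 tested in the authors' deposited table (Fisher's exact test, adjusted p = 0.0441; camera adjusted p = 0.12, and 0.017 on ranks, downward). The shortage of calls did not pass in 4 alternatives by Fisher's exact test. Its adjusted p was 0.152 with calls under 0.01, 0.124 at a mean normalized count of at least 100, 0.24 where the 95% interval excludes 0 and 0.393 above 0 in both groups.

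Markers of other cell types were counted in the same way. In the authors' deposited table, 3 of 27 tested glial markers were higher, drpr by 1.63 ± 0.36 in log2 units and gcm and pnt with WT listed at 0 (camera adjusted p = 0.283). drpr overlaps CG18171, called in the same direction. One of 22 photoreceptor markers (inaF-B, camera adjusted p = 0.136, and 0.0184 on ranks, upward), 1 of 25 blood, fat body and muscle markers (Fbp2, 0.419) and 1 of 30 cell cycle genes (CycD, 0.402) were higher in the authors' deposited table. Of 23 heat shock and stress genes 1 was higher in the authors' deposited table, Hsp70Ab, which has near-identical copies (camera adjusted p = 0.527). No gene was called among 14 cell death genes, 15 activity-regulated genes and 5 genes that tell the sex of the animals in the authors' deposited table (camera adjusted p = 0.435, 0.288 and 0.419). Adjusted over the list alone, the calls numbered 9 of 20 for dpr, 9 of 20 for the beat and side families (4 called over all genes), 11 of 24 for leucine-rich-repeat proteins, 17 of 44 for adhesion, 9 of 33 for ion channels, 12 of 40 for neurotransmitter receptors, 11 of 35 for neuropeptides and 9 of 29 for ecdysone genes in the authors' deposited table. They numbered 6 of 13 for the mitochondrial genome, 4 of 38 for the presynaptic list and 0 of 22 for photoreceptor markers, and in the other lists they stayed as counted above. Of the genes named here, svp, ct, dpr8, side-VIII, Sap47, sNPF-R, mamo, Eip78C, inaF-B and Hsp70Ab did not pass an adjusted p of 0.01 in the authors' deposited table. ct, mamo and Eip78C also lost their call among genes above 0 in both groups (adjusted p = 0.0832, 0.0613 and 0.0563). With calls at an adjusted p under 0.01, the excess of calls held for the dpr, leucine-rich-repeat, adhesion and neuropeptide lists (Fisher's exact tests). Its adjusted p was 0.0966 for ion channels and the mitochondrial genome and 0.152 for neurotransmitter receptors and ecdysone genes (Fisher's exact tests). The neuropeptide excess did not pass above 0 in both groups (Fisher's exact test, adjusted p = 0.214). Neuropeptide calls under 0.01 include Ilp1, Ilp2 and Ilp3, whose reads are of uncertain origin. They also include TkR99D, 1 of the 21 genes whose annotation is missing or belongs to another gene.

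**Figure D3:**
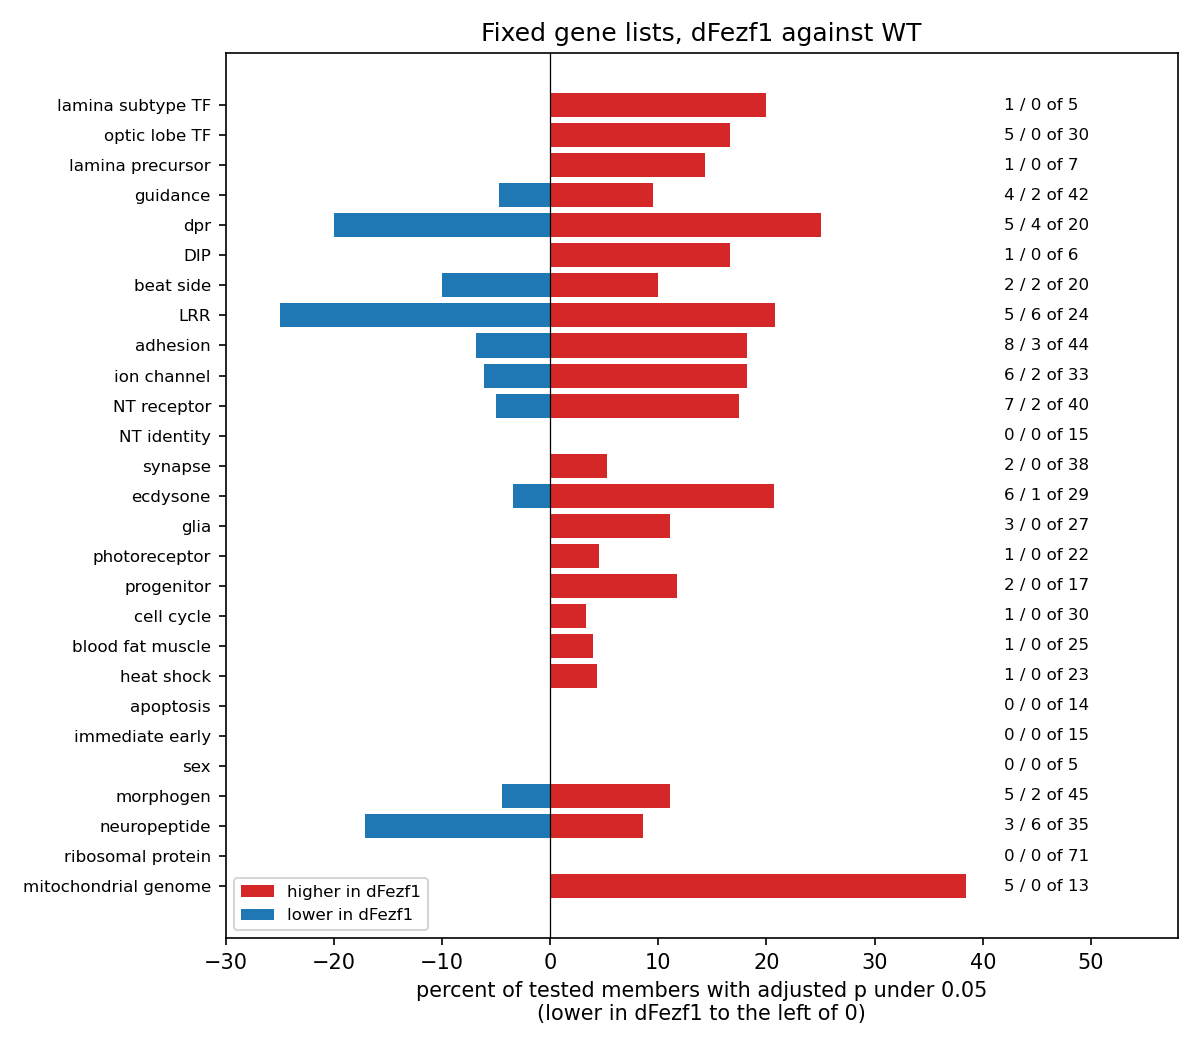
Bars give the percent of tested members of each fixed list with an adjusted p under 0.05 in the authors' deposited table, to the right of 0 for genes higher in dFezf1 and to the left for genes lower, with the counts (higher / lower of tested) beside them. The mitochondrial genome (5 of 13 higher), the dpr list (5 higher and 4 lower of 20) and the leucine-rich-repeat list (5 higher and 6 lower of 24) had long bars.

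Among called genes with a 95% interval that excludes 0 and a mean normalized count of at least 118.7, the 10 with the greatest rise in the authors' deposited table were CG15465, CG6154, Eip63F-1, Cyp6a2, CG45263, alpha-Man-IIb, dpr13, unc-13-4A, CG2082 and CG11357. CG15465, CG6154, Eip63F-1, Cyp6a2, alpha-Man-IIb and CG11357 were listed at 0 in WT in the authors' deposited table, while CG2082 rose by 7.18 ± 0.49 and CG45263 by 7.85 ± 0.57 in log2 units. The 10 with the greatest fall in the authors' deposited table were CG32052, side-III, CG13579, NetB, Ilp1, CG3014, G6P, Zasp67, smog and aPKC. CG32052 was listed at 195 in WT and 0 in dFezf1 in the authors' mean abundance, and smog fell by 4.47 ± 0.41 and aPKC, a cell polarity kinase gene, by 4.22 ± 0.41 on the log2 scale of the authors' deposited table. CG15465 overlaps CG5062, called in the same direction. In the annotation of build BDGP6 Ilp1 and Zasp67 lie within the span of CG32052, though not by the positions in the authors' deposited table. Whether the falls of these genes are separate is therefore uncertain.

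By the gene categories in the authors' deposited table, 106 of 636 tested cell surface genes were called, 67 higher and 39 lower, or 16.7% against 6.84% of all tested genes with an annotation (odds ratio 3.07, 95% interval 2.42 to 3.87, Fisher's exact test, adjusted p = 1.63e-17). Among genes with a mean normalized count of at least 100 the odds ratio was 5.8. Transcription factors were called in 36 of 567 cases in the authors' deposited table, 32 higher and 4 lower (odds ratio 0.919, 95% interval 0.63 to 1.3, Fisher's exact test, adjusted p = 1). Taken apart by direction, the share lower was smaller than among other genes (odds ratio 0.262, 95% interval 0.0706 to 0.685, Fisher's exact test, adjusted p = 0.0164) and the share higher did not pass (adjusted p = 0.352). With calls under 0.01 the lower share had an adjusted p of 0.0241. It did not pass at a mean normalized count of at least 100 (0.956), where the 95% interval excludes 0 (0.887) or above 0 in both groups (0.521). Membrane transporters were called in 45 of 493 cases in the authors' deposited table (Fisher's exact test, adjusted p = 0.231). At a mean normalized count of at least 100 they were called in 25 of 271 cases (odds ratio 1.98, Fisher's exact test, adjusted p = 0.0322). Transporters higher in dFezf1, tested apart, had an adjusted p of 0.157 by Fisher's exact test among all tested genes. It was 0.00456 at that count, 0.0285 where the 95% interval excludes 0, 0.0178 above 0 in both groups and 0.732 with calls under 0.01. Genes are not independent replicates, so these tests describe the gene lists of this comparison.

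Because the allele and the FRT40 site lie on chromosome arm 2L, calls were counted by arm. On 2L 141 of 1667 tested genes were called in the authors' deposited table (8.46%), against 488 of 7583 on the other arms (6.44%), an odds ratio of 1.34 (95% interval 1.1 to 1.64, two-sided Fisher's exact test, p = 0.00368, adjusted p = 0.0221 over 6 chromosome arms). For genes lower in dFezf1 the odds ratio was 1.57 (Fisher's exact test, p = 0.00419) and for genes higher 1.19 (Fisher's exact test, p = 0.161). With calls whose 95% interval excludes 0 the odds ratio was 1.29 (Fisher's exact test, p = 0.0558). slp1, kek1, kek3, Fas3, Pvf3, smog, G6P and chinmo are among the called genes on 2L.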

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

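An adjusted p under 0.01 and the absence of a filter on low counts were planned; the other alternatives here, and the tests of calls in lists, were chosen after the data were seen. Calls numbered 359 (223 higher, 136 lower) where the 95% interval of the fold change excludes 0, 297 (190, 107) at a mean normalized count of at least 100, 399 (254, 145) at a log2 fold change of at least 1 in size and 254 (159, 95) with both group means above 0. At a count of at least 100, 5861 genes were tested, and each of these settings removes genes by construction. The 3 other alternatives gave 474 to 657 calls. The percent of calls higher in dFezf1 stayed between 62.1 and 64.6 in these alternatives. The odds ratio of calls on 2L was 1.29 (Fisher's exact test, p = 0.0558) where the 95% interval excludes 0 and 1.26 (Fisher's exact test, p = 0.0691) at a log2 fold change of at least 1; the cause was not tested. The camera test called 8 of 27 lists with a preset correlation of 0.01 and 0 with 0.05, where a larger correlation widens the test by construction. Lists with more calls than other genes numbered 8, and 4 at an adjusted p under 0.01, where fewer genes are called. Of 80 named genes other than erm with an adjusted p, 15 lost their call under the 95% interval and 7 at 0.01. With no filter on low counts 1 lost it, the photoreceptor marker inaF-B. erm passed in none of the alternatives. No paired analysis was possible because the labels give no replicate numbers, and values per library were not used. The edgeR, DESeq2 and limma-voom fits on counts, their scalings, the stricter filter by library, the 1.5-fold test, left-out replicates, fry, the estimated correlation and the overlap of a refit with the authors' comparison were not run, since values per library were not used. Splits of the samples were not counted for the same reason, so how often chance gives as many calls stays untested.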

Other observations

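Tests chosen only after the result was seen were those of low counts, of linked variants on 2L, of cell stress, of overlap between called neighbours and both tests of the insulin-like peptide genes. The gene fmt, in the authors' deposited table, took 21.4% of the summed mean normalized counts, and the 10 most abundant genes took 28.4%. Its log2 fold change in the authors' deposited table was 0.30 ± 0.42 (SE) with an adjusted p of 0.829.

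Called genes lay beside each other more often than random placement gives. Of the tested genes in order along the chromosome arms, 52 adjacent pairs were called in the same direction in the authors' deposited table, against a median of 23 (95% range 14 to 32) in 10000 random placements of the calls within 10 classes of the mean normalized count (permutation test, p = 0.0001, the smallest these can give). With calls whose 95% interval excludes 0 there were 20 pairs against a median of 7 (permutation test, p = 0.0001). In 17 of the 52 pairs the genes overlap, and in 7 more both overlap a further gene called the same way, so reads counted for several genes may add to the excess. Among pairs that share no position with each other or with 1 further tested gene there were 27 against a median of 17 (95% range 10 to 26, permutation test, p = 0.01). With calls whose 95% interval excludes 0 there were 5 of these against a median of 5 (permutation test, p = 0.7). Whether neighbouring genes change together or reads of overlapping genes make the excess therefore stays open. TrissinR, rau and bchs on 2L, all higher in the authors' deposited table, and trn and caps on 3L, both lower, are adjacent among tested genes without overlap, though bchs overlaps CG14000, also called higher.

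The fall of Ilp1, Ilp2 and Ilp3 sits in such a cluster. Within the 21.7 kb span of CG32052 on 3L, 5 of 5 tested genes (Zasp67, Ilp1, Ilp2, Ilp3 and Ilp4) had a log2 fold change below 0 in the authors' deposited table, 4 of them called. Their mean normalized counts in the authors' deposited table were 558 for Zasp67, 239 for Ilp1, 67.7 for Ilp2, 47.0 for Ilp3 and 31.0 for Ilp4, against 12820 for CG32052. As a hypothesis, reads from CG32052, whose span holds the genes, may have been counted for them. By the positions in the authors' deposited table that span holds only 3 of the 5 (Ilp2, Ilp3 and Ilp4), and which annotation the counts rest on is not given in the sources used here, so this stays open. Fewer insulin-producing cells or less of their RNA, which the sort would remove, also stays open. Of Ilp5 and Dsk, also made by those cells, 0 were called lower. Neither had a normalized count in any library of the authors' deposited table, WT included, so neither could fall. From these genes the WT libraries thus gave no sign of insulin-producing cells.

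Of the calls in the authors' deposited table, 281 had a fold change whose 95% interval includes 0. They sit at low counts: 5.69% had a mean normalized count of at least 100, against 84.7% of the other calls. This cannot show that low counts account for them, since shrinkage itself brings fold changes near 0 in genes with few reads. The median fold change of the 281 was 0.538 in size with a median SE of 0.587. gcm, robo2, ey and TfAP-2 each had 0.54 with an SE of 0.59, at mean normalized counts from 22.0 to 45.3. Why such values recur was not tested. The median statistic of the 281 was larger in size, 5.55 against 4 for the other calls in the authors' deposited table. A group listed at 0 does not alone make a call, since 61.6% of 500 tested genes with a group at 0 and a count in the same range were called in the authors' deposited table. That share lies between the bounds set beforehand, so its part stays open, and no biological explanation was tested.

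The excess of calls on 2L may come from variants linked to the FRT40 arm or from the mutation, and the design confounds these. Among genes with a mean normalized count of at least 100 the odds ratio was 1.5 (95% interval 1.12 to 2, Fisher's exact test, p = 0.00648). This repeats the excess on part of the same genes, and the mutation could give it too, so the 2 cannot be told apart. Expression level of the genes on the arm is argued against, because the odds ratio stratified by 10 classes of the mean normalized count was 1.32 (95% interval 1.08 to 1.61). Genes within 1 Mb of erm were called in 11 of 147 cases in the authors' deposited table (odds ratio 0.865, 95% interval 0.411 to 1.65, Fisher's exact test, p = 0.757), too few to decide for variants near erm.

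Of 13 tested transcripts of the mitochondrial genome 5 were called higher in the authors' deposited table, and the shift of the set was lost with a preset correlation of 0.05 (camera adjusted p = 0.0804). No nuclear gene for a respiratory chain subunit was called. The 69 tested nuclear genes had a mean log2 fold change of -0.18 (95% interval -0.26 to -0.10) in the authors' deposited table, against 1.63 for the smallest called mitochondrial transcript, which argues against a rise of the whole chain. That interval, like the one below for the stress list, comes from the spread between genes, which are not independent replicates of the genotypes. Cell stress stays open: the stress list had a mean log2 fold change of 0.23 (95% interval -0.03 to 0.49) in the authors' deposited table, with 1 of 23 called (camera on the authors' statistic, p = 0.507). The bound of this test, 0, was set after the result was seen. An earlier bound, the 1.63 of the smallest called mitochondrial transcript, lies above that interval, but stress need not raise both sets by the same amount. RNA quality per library and the dates in the titles, which differ between the genotypes, could also contribute and were not tested.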
